A study of Mus musculus with 8 samples.

How the data were processed

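Gastrocnemius RNA of C57BL/6 mice was measured in 8 libraries made from 500 ng of RNA with the Lexogen QuantSeq 3' mRNA kit. The labels list an age of 4 weeks beside 2 weeks of tumour growth and 2 weeks of dosing. The listed age is therefore not taken as the age at dissection. Per the labels, mice received 100 µl of saline or Lewis lung carcinoma cells under the skin, and then 200 µl of water or extract by mouth daily for 2 weeks. Each deposited file holds raw read counts per gene symbol for 1 library, without normalization. The submitters' processing notes name Bowtie2, edgeR and build mm10, without versions, and do not state the counting tool, the strand counted or the annotation. Each file held 23282 rows. The counts are whole numbers that sum to between 9528011 and 12333767 per library.

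Counts of the 35 symbols listed more than once, with 44 extra rows, were kept as listed under separate names. Of the 23282 rows, 5430 had no count in any library and 13174 passed edgeR's filterByExpr with its default settings. Libraries were grouped by their titles: 3 Normal, 3 Control and 2 RP. The names and headers of the 6 Normal and Control files carry the other group's name, and no file was moved between groups. Positions came from the RefSeq annotation of build mm10, in which 12551 tested symbols matched directly, 584 matched by a synonym and 39 did not match. Among the genes named, Fbxo32, Casq1, Nrep, Sypl2, Dbp, Pfkfb1, Il1b, Nfkb1, Folr2, Zbtb16, Fam134b, Bnip3, Myh7, Saa3, Chad, Mest, Ndn, Odc1, Rian and Smox overlap another gene, from which their counts cannot be fully separated because the strand counted is not stated. The 3' ends of Amd1, Amd2, Acot1, Acot2, BC100530, Bnip3, Chil3, Foxo1, Hba-a1, Myh4, Myh7, Myl1, Oaz2, Odc1, Psmd11 and Saa3 share part of their sequence with another gene, where short reads may be counted for either.

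Genes were tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood test, TMM normalization, all 8 libraries in 1 fit, common biological coefficient of variation 0.195), 2-sided, with Benjamini-Hochberg adjustment over the 13174 genes in each comparison and a threshold of 0.05. Gene lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01 on log2 CPM with a prior count of 2, 2-sided and adjusted over the 31 lists in each comparison. All 31 lists, the comparisons, the rule for named genes and most alternatives were fixed before the data were examined. The rule took, per comparison, up to 8 higher and 8 lower genes with the largest change, a mean CPM of at least 5 and no overlap between groups, up to 3 members of each list, and 14 fixed genes such as Fbxo32, Trim63, Nfkb1 and S100a8. A fold against a group with no count was given as a bound from a floor of 3 counts over the group. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

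Alternatives were RLE and upper-quartile normalization, no filter, a mean CPM of at least 5, DESeq2 1.42.0, limma-voom, only the 2 groups compared, a replicate block, thresholds of 0.1 and of 1.5-fold, and leaving out each library. For lists they were camera with an estimated correlation, fry, RLE normalization, a replicate block and leaving out each library. Removal of haemoglobin genes and Rn45s and log2 Hba-a1 as a covariate were added after the data were seen. So were the count of genes changed in both comparisons with the Normal-titled libraries and the position of held-out libraries. When an RP library was left out, the lone RP library was assumed to vary like the other groups. The pipeline was tested on simulated data with known changes: in the Control against Normal design it recovered 11.9, 68.7 and 100% of genes changed 1.5-fold, 2-fold and 4-fold, and 8.40% of its calls were false. In the RP against Control design these were 10.4, 56.7 and 100%, with 6.72% false, and in the RP against Normal design 7.46, 58.2 and 98.5%, with 9.17% false. Figures were drawn with matplotlib 3.10.9.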

Results

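Messenger RNA was measured in the gastrocnemius, a calf muscle, of C57BL/6 mice by sequencing the 3' ends of transcripts. The series addressed cancer cachexia, the wasting of muscle that accompanies a tumour, and asked how an extract of the peony Paeonia lactiflora acts on muscular NF-kB signalling and on muscle E3 ubiquitin ligases, the enzymes that mark proteins for degradation. By their titles, 3 libraries named Normal came from mice injected with saline and 3 named Control came from water-treated mice bearing Lewis lung carcinoma, a mouse lung tumour line. The other 2 libraries, named RP, came from tumour-bearing mice given 100 mg/kg of a 30% ethanol extract of the plant daily for 2 weeks. Each library held between 9528011 and 12333767 counts. The labels do not say whether each library is a separate animal, so the p-values measure the spread between these samples.

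The labels of 6 of the 8 libraries conflict. Libraries were grouped by their titles, but the names and column headers of all 6 deposited tables of the Normal and Control samples carry the other group's name. Every direction below is therefore given for libraries titled Normal or titled Control, and a library is named by its titled group and replicate (Normal 1). If the table names hold and the titles do not, the comparison of these groups changes sign and the comparisons of RP with each of them exchange places.

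Principal component 1 held 39.1% of the variance of log2 CPM (counts scaled to library size) and separated the Normal-titled from the Control-titled libraries, with both RP libraries between them. Principal component 3 (12.9% of variance) set RP apart from both groups. RP 1 and 2 stood at -37.6 and -17.15 on it, the Normal-titled libraries at -7.65 to 12.4 and the Control-titled at 5.21 to 20.6. Across genes, the log2 CPM of libraries correlated with r of 0.979 to 0.981 within the Control-titled group, 0.956 to 0.972 within the Normal-titled group, 0.969 between the RP libraries and 0.940 to 0.951 between Normal-titled and Control-titled libraries. Haemoglobin genes held 11.3% ± 7.72 (SD, n = 3) of counts in the Normal-titled libraries, from 4.57 to 19.7%, against 1.41 to 1.61% in the Control-titled libraries. The RP libraries held 0.862% and 3.83%, and the 95% Wilson interval of each library's share reached at most 0.0222 percentage points to either side.

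**Figure D1:**
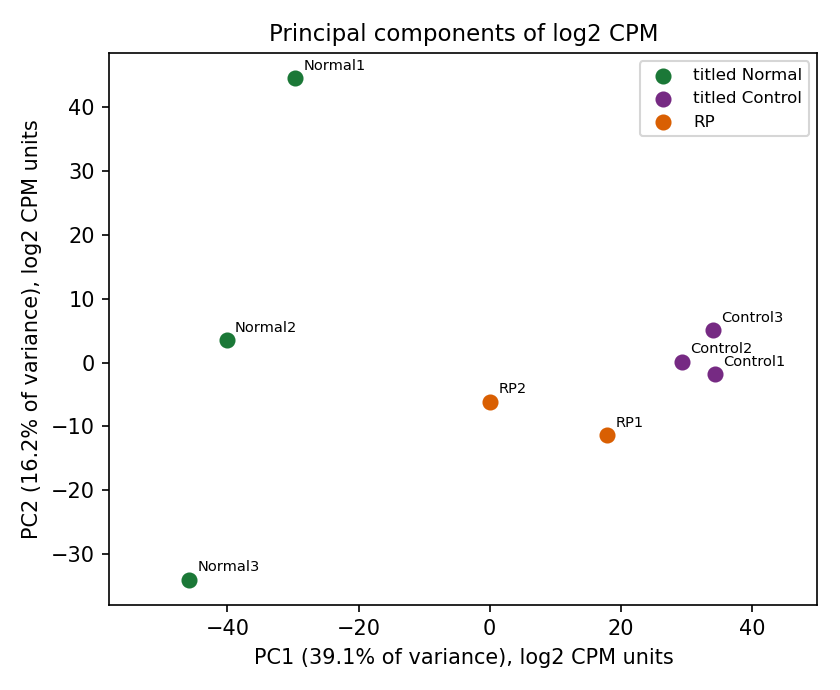
Each point is 1 library placed by principal component 1 (x axis, 39.1% of variance) and principal component 2 (y axis, 16.2% of variance) of log2 CPM. The Control-titled libraries sit between 29.3 and 34.3 on the x axis, the Normal-titled libraries between -45.8 and -29.7, and RP libraries 1 and 2 at 17.9 and 0.019.

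The comparison of the Control-titled with the Normal-titled libraries addressed the effect of the tumour on muscle. Libraries titled Normal had the higher levels of the muscle-specific E3 ubiquitin ligases Fbxo32 (atrogin-1) and Trim63 (MuRF1), of neutrophil and red-cell transcripts and of the metallothioneins Mt1 and Mt2. Libraries titled Control had the higher levels of the collagens Col3a1 and Col6a2, of the tendon genes Kera and Tnmd and of the cardiac actin gene Actc1. Fbxo32 was at 1143 ± 383 CPM (SD, n = 3) in the Normal-titled and 165 ± 12.5 CPM (SD, n = 3) in the Control-titled libraries, and Trim63 was at 1411 ± 438 and 274 ± 35.6 CPM. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1376 of 13174 genes differed, 658 higher and 718 lower in the Control-titled libraries. With upper-quartile normalization the count was also 1376, but 761 were higher and 615 lower, and 1273 were shared. With log2 Hba-a1 as a covariate, a setting added after the data were seen, the count was 382 (141 higher and 241 lower). Of these, 287 were among the 1376 of the main fit. The count of 1376 was not stable when 1 library was left out. It was 805 without Normal 2, and 609, 846 and 608 without Control 1, 2 and 3.

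**Figure D2:**
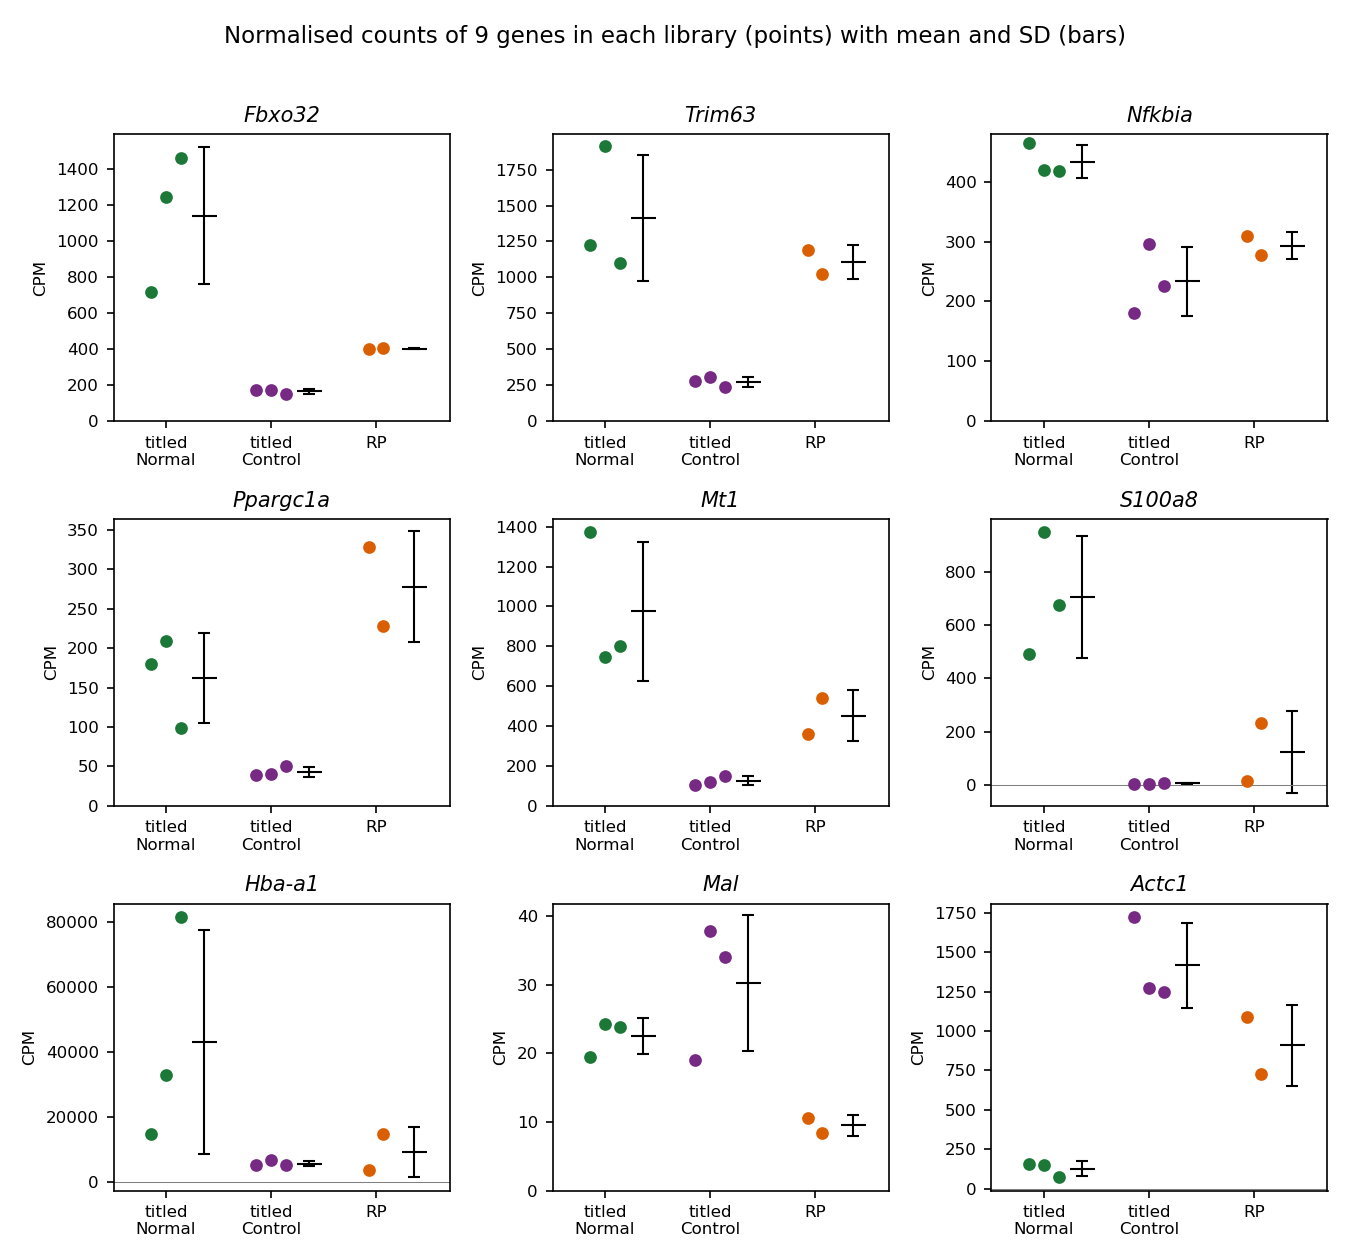
Each panel plots the TMM-normalised CPM (y axis) of 1 gene in every library (points) by group (x axis), with the group mean and SD as a bar, n = 3 titled Normal, n = 3 titled Control and n = 2 RP. Fbxo32 lies at 1143 ± 383, 165 ± 12.5 and 402 ± 2.66 CPM in the 3 groups, and S100a8 at 15.4 CPM in RP library 1 and 233 CPM in RP library 2.

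Of the E3 ubiquitin ligases and adaptors linked to muscle atrophy, 1 of 23 measured members was higher and 5 lower (1 and 6 adjusted over the list alone). The E3 ligase list had a median log2 change of -0.26 (camera adjusted p = 0.00459, adjusted p = 0.159 with an estimated correlation). The log2 change was -2.79 ± 0.227 (SE), adjusted p = 2.49e-05, for Fbxo32 (chromosome 15, 58175879 to 58214892, build mm10) and -2.36 ± 0.211 (SE), adjusted p = 3.20e-05, for Trim63 (chromosome 4, 134315120 to 134329629). Fbxo30 did not pass, with a log2 change of -0.26 ± 0.194 (SE) and adjusted p = 0.426. With the Hba-a1 covariate the log2 changes of Fbxo32 and Trim63 were -2.11 and -2.56 (adjusted p = 0.00284 and 0.00217 in edgeR), the highest adjusted p of either gene over the 18 alternatives.

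For the NF-kB pathway and its targets, 0 of 41 measured members were higher and 2 lower (0 and 2 adjusted over the list alone). The NF-kB list had a median log2 change of -0.14 (camera adjusted p = 0.166, adjusted p = 0.591 with an estimated correlation). The members that passed were Nfkbia, which encodes the NF-kB inhibitor IkBa and is itself a target, and the cytokine gene Il1b. Nfkbia (chromosome 12, 55489409 to 55492647) was at 434 ± 27.0 CPM in the Normal-titled and 234 ± 57.5 CPM in the Control-titled libraries (log2 change -0.89 ± 0.174 (SE), adjusted p = 0.00586), and Il1b, which is also among the neutrophil markers, had a log2 change of -4.53 ± 0.777 (SE), adjusted p = 0.00286. The list passed without Normal 3 (adjusted p = 0.0380). The log2 changes of Nfkb1, Rela and Ikbkb were 0.36, -0.14 and 0.029, with adjusted p = 0.231, 0.577 and 0.948.

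The FoxO, glucocorticoid and IL-6 lists shifted lower in camera at the preset correlation in the Control-titled libraries, which held 1.41 to 1.61% of counts in haemoglobin genes against 4.57 to 19.7%. Of the FoxO target and catabolic genes, 0 of 23 measured members were higher and 13 lower (2 and 17 adjusted over the list alone). The FoxO and catabolic list had a median log2 change of -0.76 (camera adjusted p = 2.32e-06, adjusted p = 0.159 with an estimated correlation). Among them were the cell cycle inhibitor Cdkn1a (log2 change -2.51), the translation repressor Eif4ebp1 (-2.01) and Ppargc1a (-1.92), a coactivator of mitochondrial genes. Foxo1 had a log2 change of -0.75 with adjusted p = 0.0269, but did not pass without Normal 3, Control 1 or Control 2 (adjusted p = 0.0620, 0.137 and 0.0831, respectively), and Foxo3 was too low to be tested. Of the glucocorticoid response genes, 0 of 21 measured members were higher and 11 lower (0 and 12 adjusted over the list alone), led by Lcn2 (-3.97), Mt2 (-3.41) and Mt1 (-2.95). Lcn2 is also among the neutrophil markers and the IL-6, STAT3 and acute-phase genes. The glucocorticoid response list had a median log2 change of -0.57 (camera adjusted p = 1.27e-06, adjusted p = 0.159 with an estimated correlation). Of the IL-6, STAT3 and acute-phase genes, 1 of 24 measured members was higher and 11 lower (2 and 14 adjusted over the list alone), including the serum amyloid gene Saa3 (-4.13). The IL-6, STAT3 and acute-phase list had a median log2 change of -0.77 (camera adjusted p = 6.09e-06, adjusted p = 0.246 with an estimated correlation).

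For the proteasome, 0 of 41 measured members were higher and 17 lower (2 and 27 adjusted over the list alone). The proteasome list had a median log2 change of -0.47 (camera adjusted p = 8.66e-10, adjusted p = 0.344 with an estimated correlation). The subunit genes Psmd8 and Psmd11 had log2 changes of -1.34 and -1.20. For autophagy and lysosome genes, 1 of 30 measured members was higher and 7 lower (1 and 8 adjusted over the list alone), with Bnip3, a mitophagy receptor, at -0.88 and Trp53inp2, an autophagy regulator, at 1.27. The autophagy and lysosome list had a median log2 change of -0.22 (camera adjusted p = 0.00380, adjusted p = 0.159 with an estimated correlation). For the integrated stress response, 2 of 20 measured members were higher and 7 lower (2 and 9 adjusted over the list alone). The integrated stress response list had a median log2 change of -0.34 (camera adjusted p = 0.00250, adjusted p = 0.159 with an estimated correlation). For denervation-responsive genes, 1 of 20 measured members was higher and 8 lower (3 and 11 adjusted over the list alone), with Mt1, Mt2 and Ankrd1 among those lower; Ankrd1 had a log2 change of -3.65 and did not pass without Control 3 (adjusted p = 0.0805). The denervation-responsive list had a median log2 change of -0.67 (camera adjusted p = 0.00467, adjusted p = 0.159 with an estimated correlation). For immediate-early genes, 1 of 26 measured members was higher and 6 lower (1 and 8 adjusted over the list alone), led by the nuclear receptor Nr4a3 (-4.54). The immediate-early list had a median log2 change of -0.31 (camera adjusted p = 0.00648, adjusted p = 0.493 with an estimated correlation). It did not pass without Control 3 (adjusted p = 0.125).

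Energy and fibre genes moved in both directions. Of the oxidative phosphorylation genes, 7 of 65 measured members were higher and 0 lower (8 and 0 adjusted over the list alone), with the cytochrome oxidase subunit Cox7a1 at 0.90. The oxidative phosphorylation list had a median log2 change of 0.28 (camera adjusted p = 3.87e-08, adjusted p = 0.255 with an estimated correlation). Of the glycolysis and glycogen genes, 8 of 29 measured members were higher and 2 lower (10 and 5 adjusted over the list alone), with Pgam2 and Pfkfb1 higher (1.01 and 1.09) and hexokinase Hk2 lower (-1.10). The glycolysis and glycogen list had a median log2 change of 0.34 (camera adjusted p = 0.0158, adjusted p = 0.444 with an estimated correlation). Of the fatty acid oxidation and PPAR target genes, 0 of 35 measured members were higher and 7 lower (1 and 11 adjusted over the list alone), with the acyl-CoA thioesterases Acot1, whose 3' end shares sequence with Acot2, and Acot2 at -2.59 and -1.95. The fatty acid oxidation list had a median log2 change of -0.29 (camera adjusted p = 1.16e-04, adjusted p = 0.444 with an estimated correlation). Of the fast-fibre genes, 6 of 19 measured members were higher and 1 lower (7 and 1 adjusted over the list alone), led by Sypl2 (1.80), the calcium store protein Casq1 (1.72) and the light chain Myl1 (1.35). The fast-fibre list had a median log2 change of 0.13 (camera adjusted p = 0.00629, adjusted p = 0.533 with an estimated correlation). The glycolysis list did not pass without Normal 1 (adjusted p = 0.0575), nor the fast-fibre list without Normal 1 (adjusted p = 0.129). The level of the fast-fibre list, the mean log2 CPM of its members against their mean over the 8 libraries, was 0.082, 0.24 and 0.0047 in Control 1, 2 and 3 and -0.49, -0.37 and 0.029 in Normal 1, 2 and 3, so the groups overlapped. For slow-fibre genes, 1 of 16 measured members was higher and 3 lower (1 and 3 adjusted over the list alone), and the stress-responsive muscle genes Csrp3 and Ankrd2 were lower (-1.46 and -1.15). The slow-fibre list had a median log2 change of -0.084 (camera adjusted p = 0.391, adjusted p = 0.695 with an estimated correlation). The myosin genes Myh4 and Myh7 did not pass (log2 changes -0.22 and -0.25, adjusted p = 0.539 and 0.429).

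Actc1 (chromosome 2, 114047282 to 114052875) was at 126 ± 48.2 CPM in the Normal-titled and 1416 ± 268 CPM in the Control-titled libraries, a log2 change of 3.49 ± 0.291 (SE), adjusted p = 3.03e-05. Nrep, Clec11a and 1500015O10Rik had log2 changes of 3.10, 2.90 and 3.08. Of the collagen and matrix genes, 16 of 44 measured members were higher and 4 lower (21 and 6 adjusted over the list alone), with Col3a1 at 2.85, Col6a2 at 2.82 and Thbs1, which platelets also carry, at -2.89. The collagen and matrix list had a median log2 change of 0.57 (camera adjusted p = 4.71e-05, adjusted p = 0.559 with an estimated correlation). Its level was 0.26, -0.17 and -1.10 in Normal 1, 2 and 3 and 0.29 to 0.40 in the Control-titled libraries, so Normal 1 lay close to the latter. Of the fibro-adipogenic progenitor and tenocyte markers, 9 of 23 measured members were higher and 0 lower (10 and 1 adjusted over the list alone), with Kera at 3.23 and Tnmd at 2.85. The fibro-adipogenic and tenocyte list had a median log2 change of 0.42 (camera adjusted p = 8.31e-05, adjusted p = 0.475 with an estimated correlation). It stood at 0.020, -0.34 and -0.97 in Normal 1, 2 and 3 and 0.29 to 0.32 in the Control-titled libraries. For satellite cell and regeneration genes, 1 of 23 measured members was higher and 5 lower (1 and 6 adjusted over the list alone), with Actc1 higher and the myogenic regulator Myod1 lower (-1.89). The satellite cell list had a median log2 change of -0.17 (camera adjusted p = 0.0951, adjusted p = 0.337 with an estimated correlation). For myostatin, activin, BMP and IGF signalling, 3 of 33 measured members were higher and 5 lower (6 and 7 adjusted over the list alone), with Igfbp5 higher (1.66), Inhbb and Igfbp3 lower (-1.79 and -1.13), and Mstn at -0.21 with adjusted p = 0.403. The growth signalling list had a median log2 change of -0.040, mean 0.041 (camera adjusted p = 0.804, adjusted p = 0.804 with an estimated correlation). The satellite cell list passed without Control 2 (adjusted p = 0.0425).

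Markers of other cell types differed as well. Neutrophil markers were far lower in the Control-titled libraries, where 0 of 18 measured members were higher and 16 lower (0 and 17 adjusted over the list alone). S100a8 (chromosome 3, 90669071 to 90670034) was at 705 ± 229.7 CPM in the Normal-titled and 5.35 ± 2.72 CPM in the Control-titled libraries (log2 change -7.04 ± 0.812 (SE), adjusted p = 1.80e-04), and S100a9 had a log2 change of -6.75. The neutrophil list had a median log2 change of -4.59 with the 4 genes at 0 in every Control-titled library set to a floor of 3 counts over the group, against -6.70 as fitted (camera adjusted p = 7.59e-16, adjusted p = 0.220 with an estimated correlation). BC100530, among these 4, was at least 26.3-fold lower. Of the erythroid markers, 0 of 17 measured members were higher and 16 lower (0 and 17 adjusted over the list alone), with the band 3 anion exchanger gene Slc4a1 at -6.97. The erythroid list had a median log2 change of -3.18 (camera adjusted p = 2.66e-12, adjusted p = 0.301 with an estimated correlation). Of the interferon response genes, 13 of 42 measured members were higher and 2 lower (20 and 4 adjusted over the list alone), although Isg20, also listed as an erythroid marker, and Rsad2 were lower (-2.78 and -2.37). The interferon response list had a median log2 change of 0.63 (camera adjusted p = 1.01e-06, adjusted p = 0.370 with an estimated correlation). The level of this list was 0.68, 0.012 and 0.23 in Control 1, 2 and 3 and 0.0089, -0.28 and -0.29 in Normal 1, 2 and 3, so Control 2 stood level with Normal 1.

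For endothelial markers, 0 of 22 measured members were higher and 5 lower (2 and 8 adjusted over the list alone), with Rgcc at -1.49 and Vwf at -0.95. The endothelial list had a median log2 change of -0.25 (camera adjusted p = 0.0412, adjusted p = 0.530 with an estimated correlation). It did not pass without Normal 1, Normal 2, Control 1 or Control 2 (adjusted p = 0.132, 0.0725, 0.0664 and 0.160, respectively), and its level was -0.090, -0.16 and 0.11 in Control 1, 2 and 3 and 0.26, 0.22 and 0.021 in Normal 1, 2 and 3, so the groups overlapped. For Schwann and nerve markers, 2 of 18 measured members were higher and 0 lower (3 and 1 adjusted over the list alone). The Schwann and nerve list had a median log2 change of 0.50 (camera adjusted p = 0.0120, adjusted p = 0.530 with an estimated correlation). It did not pass without Normal 1 or Control 2 (adjusted p = 0.0854 and 0.0776, respectively), and its level was 0.054, 0.75 and 0.64 in Control 1, 2 and 3 and -0.12, 0.12 and -0.031 in Normal 1, 2 and 3, so the groups overlapped. The macrophage and monocyte list had a median log2 change of -0.15 (camera adjusted p = 0.833, adjusted p = 0.973 with an estimated correlation), with 1 of 25 members higher and 2 lower (1 and 2 adjusted over the list alone). Folr2, a marker of resident macrophages, was higher (1.54). The adipocyte list had a median log2 change of 0.31 (camera adjusted p = 0.0951, adjusted p = 0.674 with an estimated correlation), with 2 of 23 members higher and 0 lower (1 and 0 adjusted over the list alone). The fatty acid synthase gene Fasn was higher (1.61). The lymphocyte list had a median log2 change of 0.76 (camera adjusted p = 0.152, adjusted p = 0.674 with an estimated correlation), with 0 of 7 members higher and 0 lower (0 and 0 adjusted over the list alone). The epithelial list had a median log2 change of 0.060, mean -0.11 (camera adjusted p = 0.833, adjusted p = 0.895 with an estimated correlation), with 0 of 6 members higher and 0 lower (0 and 1 adjusted over the list alone). The cell cycle list had a median log2 change of -0.0062, mean 0.044 (camera adjusted p = 0.993, adjusted p = 0.994 with an estimated correlation), with 1 of 32 members higher and 1 lower (2 and 2 adjusted over the list alone). The clock list had a median log2 change of 0.026, mean -0.0056 (camera adjusted p = 0.833, adjusted p = 0.895 with an estimated correlation), with 4 of 18 members higher and 5 lower (8 and 6 adjusted over the list alone). Among clock genes, Dbp was higher (2.03) and Nfil3 was lower (-1.37). For cytosolic ribosomal proteins, 0 of 76 measured members were higher and 1 lower (0 and 0 adjusted over the list alone), and the fitted change was below 0 in all 76. The ribosomal protein list had a median log2 change of -0.32 (camera adjusted p = 8.13e-10, adjusted p = 0.530 with an estimated correlation). Its level was -0.12, -0.072 and -0.22 in Control 1, 2 and 3 and -0.13, 0.28 and 0.41 in Normal 1, 2 and 3, so the groups overlapped. The macrophage list passed without Normal 3 (adjusted p = 0.0184), the adipocyte list without Normal 1, Control 1 or Control 2 (adjusted p = 0.0222, 0.0203 and 0.0227, respectively) and the lymphocyte list without Normal 2 or Control 2 (adjusted p = 0.00651 and 0.0326, respectively).

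The rule for named genes took 85 genes that passed in this comparison, beside 11 that did not pass. Of the 85, 43 still passed with the Hba-a1 covariate in edgeR, 40 did not and 2 turned direction without passing. Of these 42, 7 had a larger log2 change with the covariate, 24 kept at least 50% of it and 9 kept less, while the SE rose in 38, so an ended call does not by itself show that the change went with blood. Among those printed above, Nfkbia, Il1b, Foxo1, Bnip3, Psmd8, Pfkfb1, Ankrd1, Col3a1, Igfbp5, Igfbp3, Inhbb, Isg20, Rsad2, Nfil3, BC100530, Folr2, Rgcc and Vwf did not pass with it (adjusted p from 0.0539 to 0.292). The log2 changes (± SE, without to with the covariate) of Nfkbia and Vwf grew (Nfkbia -0.89 ± 0.174 to -0.997 ± 0.271 and Vwf -0.95 ± 0.202 to -1.15 ± 0.337). Changes that shrank a little while the SE rose were Ankrd1 -3.65 ± 0.833 to -3.49 ± 1.19, Rgcc -1.49 ± 0.225 to -1.41 ± 0.353 and Foxo1 -0.75 ± 0.194 to -0.65 ± 0.326. Those that shrank more while the SE rose were Pfkfb1 1.09 ± 0.191 to 0.89 ± 0.314, Nfil3 -1.37 ± 0.193 to -1.05 ± 0.304, BC100530 (as fitted with a group at 0) -7.67 ± 1.48 to -5.94 ± 2.08, Igfbp3 -1.13 ± 0.187 to -0.77 ± 0.283, Col3a1 2.85 ± 0.393 to 1.95 ± 0.605, Inhbb -1.79 ± 0.341 to -1.28 ± 0.553, Psmd8 -1.34 ± 0.205 to -0.89 ± 0.298, Folr2 1.54 ± 0.298 to 1.01 ± 0.503, Bnip3 -0.88 ± 0.156 to -0.50 ± 0.211, Igfbp5 1.66 ± 0.231 to 0.91 ± 0.259 and Il1b -4.53 ± 0.777 to -2.03 ± 0.875. In Isg20 and Rsad2 the SE fell and the change shrank (Isg20 -2.78 ± 0.439 to -0.56 ± 0.273 and Rsad2 -2.37 ± 0.329 to -0.84 ± 0.250).

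**Figure D3:**
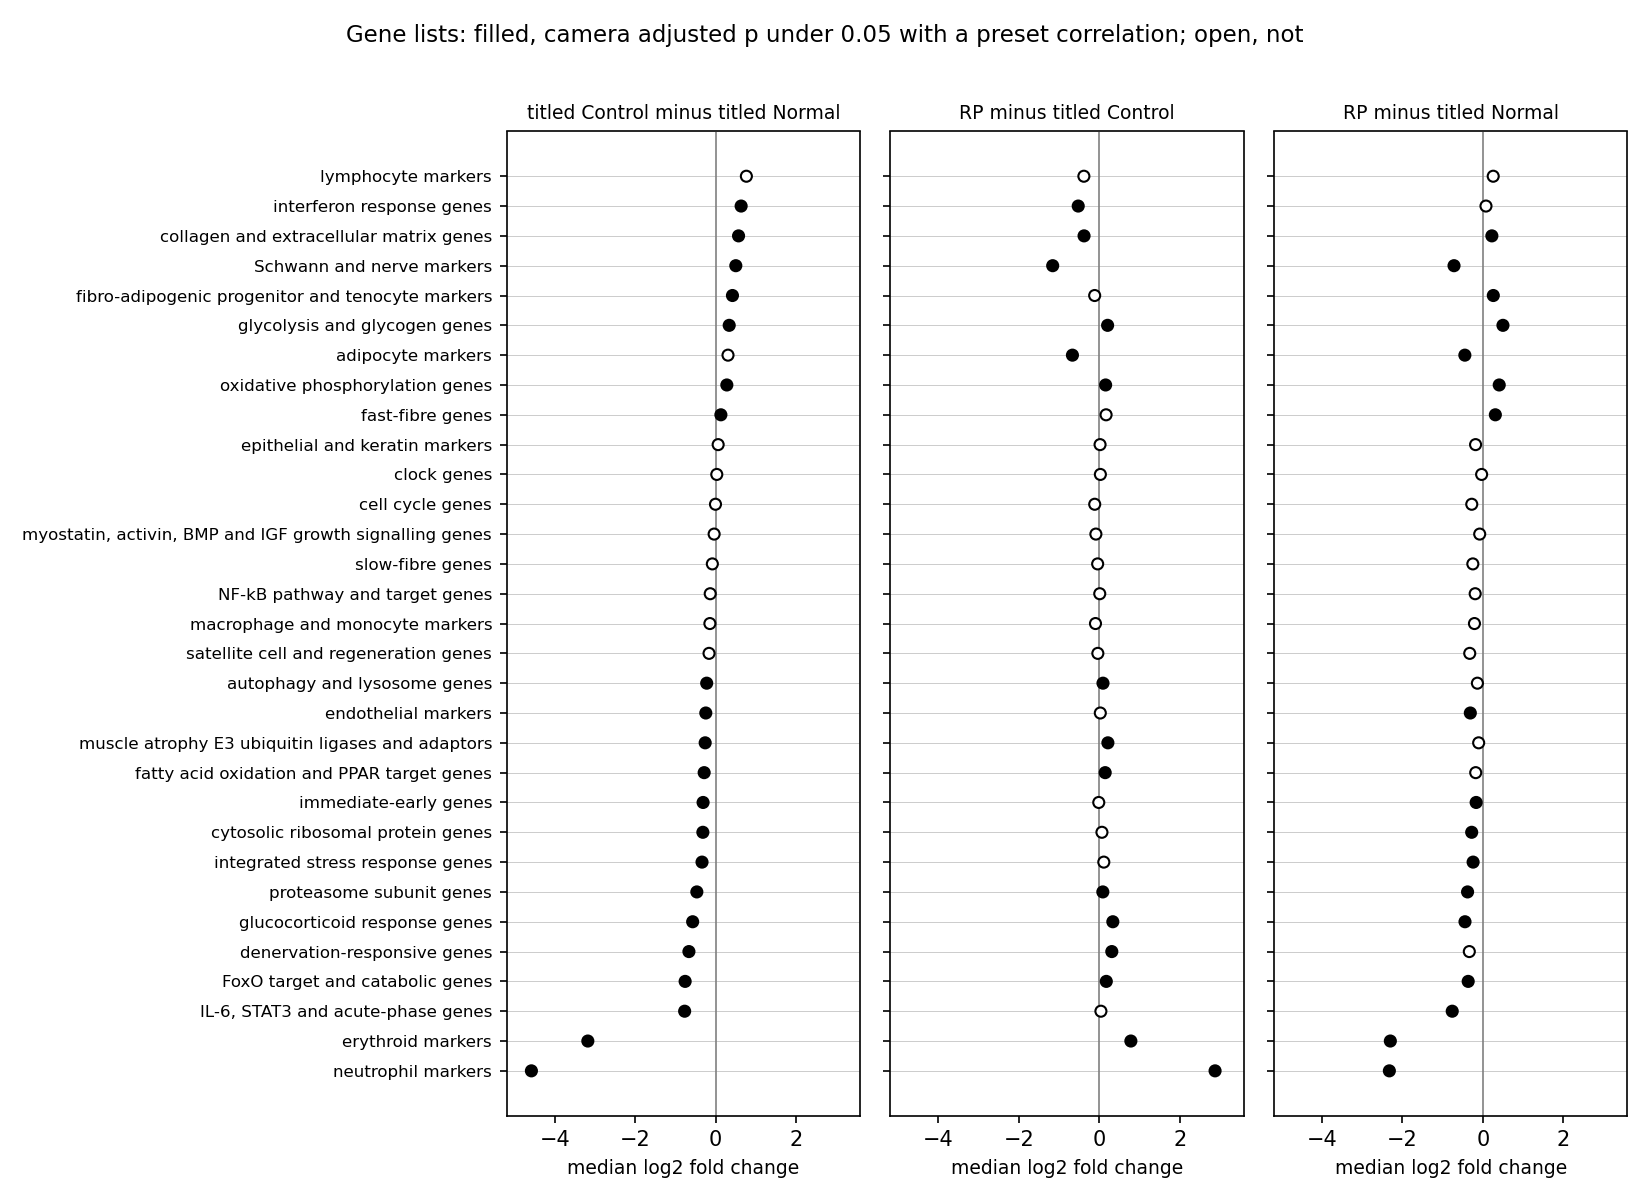
Each point is the median log2 fold change (x axis) of the measured members of 1 of 31 gene lists (y axis) in 1 of the 3 comparisons, with neutrophil genes at 0 in a whole group set to their floor. Filled points passed camera with a preset correlation (21, 15 and 17 lists from left to right), open points did not, and neutrophil markers lie at -4.59, 2.88 and -2.32.

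The comparison of RP with the Control-titled libraries addressed the effect of the extract in tumour-bearing mice. RP libraries had more Nr4a3, Ppargc1a, Trim63, Hk2 and metallothionein mRNA than the Control-titled libraries, and less mRNA of the myelin gene Mal. Nr4a3 (chromosome 4, 48045078 to 48086447), an immediate-early nuclear receptor, was at 96.7 ± 20.2 CPM (SD, n = 2) against 2.86 ± 1.87 CPM (SD, n = 3), a log2 change of 5.09 ± 0.446 (SE), adjusted p = 3.83e-04. In all, 23 of 13174 genes differed in edgeR, 19 higher and 4 lower in RP. Neither the count nor this balance was stable: without RP 2 the count was 31, 9 higher and 22 lower, with 9 of the 23 among them, and without RP 1 it was 30, 27 higher and 3 lower, with 13 of the 23. It was 204 without the low-count filter (109 higher and 95 lower), 112 with DESeq2 (64 and 48), 121 with only these groups fitted (72 and 49), 10 with limma-voom (10 and 0) and 11 with a mean CPM of at least 5 (11 and 0). It was 56, 12 and 72 without Normal 1, 2 and 3, and 15, 8 and 9 without Control 1, 2 and 3. If the table names hold, this is the comparison of RP with tumour-free mice.

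Of the muscle E3 ligases and adaptors, 1 of 23 measured members was higher and 0 lower (2 and 0 adjusted over the list alone). The E3 ligase list had a median log2 change of 0.21 (camera adjusted p = 7.23e-04, adjusted p = 0.184 with an estimated correlation). Trim63 was at 1105 ± 118 CPM in RP (log2 change 2.01 ± 0.223 (SE), adjusted p = 0.00173), higher in both RP libraries than in any Control-titled library. Fbxo32 was at 402 ± 2.66 CPM in RP and at 151 to 174 CPM in the Control-titled libraries, a log2 change of 1.28 ± 0.234 (SE). In the edgeR fit of all 8 libraries it fell just short of the threshold (adjusted p = 0.0512). With only these 2 groups fitted in edgeR it passed (adjusted p = 2.18e-04). It also passed with DESeq2 (adjusted p = 7.95e-05) and without Normal 1 or Normal 3 (adjusted p = 5.14e-04 and 0.00818, respectively). Over all 18 alternatives its adjusted p ran from 2.12e-05 to 0.334. For the NF-kB list, 0 of 41 measured members were higher and 0 lower (0 and 0 adjusted over the list alone). The NF-kB list had a median log2 change of 0.012 (camera adjusted p = 0.922, adjusted p = 0.971 with an estimated correlation). The log2 changes of Nfkbia, Nfkb1, Rela and Ikbkb were 0.33, -0.64, 0.076 and 0.30, none passing (adjusted p = 0.662, 0.341, 0.928 and 0.754).

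For glucocorticoid response genes, 3 of 21 measured members were higher and 0 lower (7 and 0 adjusted over the list alone), namely Mt2 (2.26), Mt1 (1.84) and Zbtb16 (1.03). The glucocorticoid response list had a median log2 change of 0.34 (camera adjusted p = 4.04e-06, adjusted p = 0.201 with an estimated correlation). For denervation-responsive genes, 2 of 20 measured members were higher and 0 lower (2 and 0 adjusted over the list alone), the same metallothioneins. The denervation-responsive list had a median log2 change of 0.31 (camera adjusted p = 3.26e-04, adjusted p = 0.184 with an estimated correlation). For FoxO target and catabolic genes, 1 of 23 measured members was higher and 0 lower (1 and 0 adjusted over the list alone). The FoxO and catabolic list had a median log2 change of 0.17 (camera adjusted p = 0.00281, adjusted p = 0.201 with an estimated correlation). For fatty acid oxidation and PPAR targets, 1 of 35 measured members was higher and 0 lower (1 and 0 adjusted over the list alone). The fatty acid oxidation list had a median log2 change of 0.15 (camera adjusted p = 0.00308, adjusted p = 0.679 with an estimated correlation). Both lists named Ppargc1a (chromosome 5, 51454249 to 52115853), at 278 ± 70.1 CPM in RP and 43.0 ± 6.40 CPM in the Control-titled libraries, a log2 change of 2.69 ± 0.272 (SE), adjusted p = 7.74e-04, and neither passed without RP 2 (adjusted p = 0.0595 and 0.0913). For glycolysis and glycogen, 1 of 29 measured members was higher and 0 lower (1 and 0 adjusted over the list alone), the gene being Hk2 (1.79 ± 0.202 (SE), adjusted p = 0.00173). The glycolysis and glycogen list had a median log2 change of 0.21 (camera adjusted p = 1.44e-04, adjusted p = 0.331 with an estimated correlation). For oxidative phosphorylation, 0 of 65 measured members were higher and 0 lower (0 and 0 adjusted over the list alone). The oxidative phosphorylation list had a median log2 change of 0.16 (camera adjusted p = 1.03e-05, adjusted p = 0.352 with an estimated correlation). Other genes higher in RP were Snai3 (2.59) and the ER-phagy receptor gene Fam134b (2.06). The call of Mt1 ended without Control 1, Control 2 or RP 2 (adjusted p = 0.0729, 0.112 and 0.0741, respectively), that of Mt2 without Control 1, Control 2, Control 3 or RP 2 (adjusted p = 0.0729, 0.112, 0.107 and 0.0809, respectively) and that of Zbtb16 without Normal 2, Control 1, Control 2, Control 3 or RP 1 (adjusted p = 0.0829, 0.180, 0.119, 0.245 and 0.306, respectively).

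The proteasome list had a median log2 change of 0.089 (camera adjusted p = 0.0403, adjusted p = 0.799 with an estimated correlation), with 0 of 41 members higher and 0 lower (1 and 0 adjusted over the list alone). The autophagy and lysosome list had a median log2 change of 0.093 (camera adjusted p = 0.0492, adjusted p = 0.331 with an estimated correlation), with 0 of 30 members higher and 0 lower (0 and 0 adjusted over the list alone). The proteasome call ended without Control 1, Control 3, RP 1 or RP 2 (adjusted p = 0.0947, 0.145, 0.0574 and 0.155, respectively), and the autophagy call without Control 1, Control 3, RP 1 or RP 2 (adjusted p = 0.0877, 0.0864, 0.156 and 0.0864, respectively).

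Nerve, interferon, adipocyte and matrix lists were lower in RP than in the Control-titled libraries. For Schwann and nerve markers, 0 of 18 measured members were higher and 2 lower (0 and 12 adjusted over the list alone), and the fitted change was below 0 in all 18. The Schwann and nerve list had a median log2 change of -1.16 (camera adjusted p = 3.41e-15, adjusted p = 0.201 with an estimated correlation). Mal was at 10.6 and 8.43 CPM in RP 1 and 2 and 30.3 ± 9.91 CPM in the Control-titled libraries (log2 change -1.67 ± 0.279 (SE), adjusted p = 0.0375). For interferon response genes, 0 of 42 measured members were higher and 0 lower (0 and 0 adjusted over the list alone). The interferon response list had a median log2 change of -0.52 (camera adjusted p = 4.54e-08, adjusted p = 0.352 with an estimated correlation). The level of this list was -0.14 and -0.22 in RP 1 and 2 and 0.68, 0.012 and 0.23 in Control 1, 2 and 3. For adipocyte markers, 0 of 23 measured members were higher and 0 lower (0 and 10 adjusted over the list alone). The adipocyte list had a median log2 change of -0.67 (camera adjusted p = 2.30e-06, adjusted p = 0.352 with an estimated correlation). Its level was -0.30 and -0.34 in RP 1 and 2 and 0.087, 0.076 and 0.67 in Control 1, 2 and 3, with Control 3 apart. For collagen and matrix genes, 0 of 44 measured members were higher and 0 lower (0 and 0 adjusted over the list alone). The collagen and matrix list had a median log2 change of -0.38 (camera adjusted p = 4.24e-04, adjusted p = 0.772 with an estimated correlation). The call of Mal ended without Normal 2, Control 2, Control 3, RP 1 or RP 2 (adjusted p = 0.0775, 0.151, 0.201, 0.126 and 0.173, respectively). Mal, Zbtb16, S100a8 and S100a9 also did not pass with a mean CPM of at least 5 or with limma-voom (adjusted p from 0.0624 to 0.371). With a replicate block in edgeR, Mal, Zbtb16 and S100a9 did not pass (adjusted p = 0.0544, 0.0858 and 0.0677, respectively).

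Neutrophil and haemoglobin transcripts stood at different levels in the RP libraries. S100a8 was at 15.4 and 233 CPM in RP libraries 1 and 2, against 5.35 ± 2.72 CPM in the Control-titled libraries (log2 change 4.53 ± 0.769 (SE), adjusted p = 0.0403), and haemoglobin genes held 0.862% and 3.83% of counts. The call of S100a8 ended without Normal 2, Control 1, Control 2 or Control 3 (adjusted p = 0.0825, 0.167, 0.186 and 0.201, respectively). That of S100a9 (log2 change 4.36) ended without the same libraries (adjusted p = 0.0879, 0.169, 0.203 and 0.245, respectively). With the Hba-a1 covariate in edgeR neither passed (adjusted p = 0.0523 for S100a8 and 0.0601 for S100a9). Without RP 2 the log2 changes of S100a8 and S100a9 fell to 1.53 and 1.28. For neutrophil markers, 2 of 18 measured members were higher and 0 lower (15 and 0 adjusted over the list alone), with a median log2 change of 2.88 at the floor of 3 counts over the group and 4.18 as fitted (camera adjusted p = 6.88e-09, adjusted p = 0.352 with an estimated correlation). The level of this list was -1.56 in RP 1, close to the -2.02 to -1.73 of the Control-titled libraries, and 0.96 in RP 2, and without RP 2 its adjusted p rose to 0.0438. For erythroid markers, 0 of 17 measured members were higher and 0 lower (0 and 0 adjusted over the list alone). The erythroid list had a median log2 change of 0.79 (camera adjusted p = 0.00583, adjusted p = 0.772 with an estimated correlation). It did not pass without RP 2 (adjusted p = 0.493), where its direction was down, and its level was -1.56 and 0.29 in RP 1 and 2 and -1.25, -1.17 and -1.35 in Control 1, 2 and 3, so the groups overlapped.

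The remaining lists did not pass between RP and the Control-titled libraries. The fast-fibre list had a median log2 change of 0.17 (camera adjusted p = 0.0555, adjusted p = 0.793 with an estimated correlation), with 0 of 19 members higher and 0 lower (0 and 0 adjusted over the list alone). The ribosomal protein list had a median log2 change of 0.067 (camera adjusted p = 0.0825, adjusted p = 0.940 with an estimated correlation), with 0 of 76 members higher and 0 lower (0 and 0 adjusted over the list alone). The IL-6, STAT3 and acute-phase list had a median log2 change of 0.041 (camera adjusted p = 0.114, adjusted p = 0.772 with an estimated correlation), with 0 of 24 members higher and 0 lower (5 and 1 adjusted over the list alone). The fibro-adipogenic and tenocyte list had a median log2 change of -0.11 (camera adjusted p = 0.178, adjusted p = 0.856 with an estimated correlation), with 0 of 23 members higher and 0 lower (0 and 0 adjusted over the list alone). The lymphocyte list had a median log2 change of -0.38 (camera adjusted p = 0.198, adjusted p = 0.799 with an estimated correlation), with 0 of 7 members higher and 0 lower (0 and 0 adjusted over the list alone). The integrated stress response list had a median log2 change of 0.11 (camera adjusted p = 0.244, adjusted p = 0.493 with an estimated correlation), with 0 of 20 members higher and 0 lower (1 and 0 adjusted over the list alone). The growth signalling list had a median log2 change of -0.084 (camera adjusted p = 0.369, adjusted p = 0.679 with an estimated correlation), with 0 of 33 members higher and 0 lower (0 and 0 adjusted over the list alone). The cell cycle list had a median log2 change of -0.11 (camera adjusted p = 0.337, adjusted p = 0.772 with an estimated correlation), with 0 of 32 members higher and 0 lower (0 and 0 adjusted over the list alone). The slow-fibre list had a median log2 change of -0.040 (camera adjusted p = 0.877, adjusted p = 0.971 with an estimated correlation), with 0 of 16 members higher and 0 lower (0 and 0 adjusted over the list alone). The macrophage and monocyte list had a median log2 change of -0.094 (camera adjusted p = 0.780, adjusted p = 0.971 with an estimated correlation), with 0 of 25 members higher and 0 lower (0 and 0 adjusted over the list alone). The clock list had a median log2 change of 0.028 (camera adjusted p = 0.729, adjusted p = 0.848 with an estimated correlation), with 0 of 18 members higher and 0 lower (1 and 1 adjusted over the list alone). Medians and means differed in sign in the next lists. The immediate-early list had a median log2 change of -0.012, mean 0.29 (camera adjusted p = 0.369, adjusted p = 0.862 with an estimated correlation), with 1 of 26 members higher and 0 lower (2 and 0 adjusted over the list alone). The satellite cell list had a median log2 change of -0.035, mean 0.055 (camera adjusted p = 0.922, adjusted p = 0.971 with an estimated correlation), with 0 of 23 members higher and 0 lower (0 and 0 adjusted over the list alone). The endothelial list had a median log2 change of 0.026, mean -0.14 (camera adjusted p = 0.780, adjusted p = 0.971 with an estimated correlation), with 0 of 22 members higher and 0 lower (0 and 2 adjusted over the list alone). The epithelial list had a median log2 change of 0.020, mean -0.048 (camera adjusted p = 0.984, adjusted p = 0.987 with an estimated correlation), with 0 of 6 members higher and 0 lower (0 and 0 adjusted over the list alone). The fast-fibre list passed without Normal 1, Normal 3, Control 2 or RP 2 (adjusted p = 0.0410, 0.0210, 0.00964 and 0.0440, respectively), the ribosomal list without Normal 1, Control 2 or RP 1 (adjusted p = 0.0317, 0.0212 and 2.01e-04, respectively) and the IL-6 list without Control 3 or RP 1 (adjusted p = 0.0371 and 0.00231, respectively). The immediate-early list passed without RP 1 (adjusted p = 0.00157), the macrophage list without RP 2 (adjusted p = 0.0438) and the lymphocyte list without Control 2 or RP 2 (adjusted p = 0.0277 and 0.0438, respectively).

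The comparison of RP with the Normal-titled libraries set treated tumour-bearing mice against tumour-free mice. RP libraries had more Actc1, Nrep, Kera, Casq1 and Sypl2 mRNA and less Fbxo32, Cdkn1a, neutrophil and erythroid mRNA than the Normal-titled libraries. The log2 change of Actc1 was 2.85 ± 0.299 (SE), adjusted p = 3.16e-04, that of Nrep 2.74, that of Cdkn1a -1.95 ± 0.256 (SE), adjusted p = 0.00143. In edgeR, 330 of 13174 genes differed, 220 higher and 110 lower in RP. The count was 718 without the low-count filter (398 higher and 320 lower) and 676 with DESeq2 (422 and 254). The count was 100 with only these groups fitted (75 and 25) and 104 with the Hba-a1 covariate (75 and 29). It was 670, 137 and 580 without Normal 1, 2 and 3, 204 and 197 without Control 1 and 3, and 57 without RP 1. The rule for named genes took 63 genes that passed here, beside 19 that did not pass. Of the 63, 42 did not pass with the Hba-a1 covariate. Calls also ended without RP 1 and without RP 2, where the lone RP library was assumed to vary like the other groups. If the table names hold, this is the comparison of RP with untreated tumour-bearing mice.

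Fbxo32 had a log2 change of -1.51 ± 0.250 (SE), adjusted p = 0.00658, lower in both RP libraries than in any Normal-titled library, and its call ended without RP 1 or RP 2 (adjusted p = 0.114 and 0.0513, respectively) and with the Hba-a1 covariate (adjusted p = 0.148). Over all 18 alternatives its adjusted p ran from 8.75e-08 to 0.148. Trim63 did not pass, at -0.35 ± 0.226 (SE), adjusted p = 0.467. For the E3 ligase list, 0 of 23 measured members were higher and 1 lower (0 and 1 adjusted over the list alone). The E3 ligase list had a median log2 change of -0.10 (camera adjusted p = 0.595, adjusted p = 0.655 with an estimated correlation). For the NF-kB list, 0 of 41 measured members were higher and 0 lower (0 and 0 adjusted over the list alone). The NF-kB list had a median log2 change of -0.19 (camera adjusted p = 0.167, adjusted p = 0.638 with an estimated correlation). The NF-kB list passed without RP 2 (adjusted p = 0.0267). The log2 changes of Nfkbia, Nfkb1, Rela and Ikbkb were -0.56, -0.28, -0.061 and 0.33, with adjusted p = 0.155, 0.539, 0.893 and 0.497.

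The oxidative phosphorylation, glycolysis and fast-fibre lists were higher in RP than in the Normal-titled libraries. For oxidative phosphorylation, 5 of 65 measured members were higher and 0 lower (39 and 0 adjusted over the list alone). The oxidative phosphorylation list had a median log2 change of 0.41 (camera adjusted p = 1.82e-19, adjusted p = 0.273 with an estimated correlation). For glycolysis and glycogen, 10 of 29 measured members were higher and 0 lower (19 and 3 adjusted over the list alone). The glycolysis and glycogen list had a median log2 change of 0.50 (camera adjusted p = 7.23e-08, adjusted p = 0.273 with an estimated correlation). For fast-fibre genes, 5 of 19 measured members were higher and 0 lower (7 and 1 adjusted over the list alone), led by Sypl2 (1.75), Casq1 (1.67) and the calcium buffer Pvalb (1.19). The fast-fibre list had a median log2 change of 0.31 (camera adjusted p = 1.71e-06, adjusted p = 0.438 with an estimated correlation). For fibro-adipogenic and tenocyte markers, 6 of 23 measured members were higher and 0 lower (9 and 0 adjusted over the list alone), with Kera at 2.67 and Tnmd at 2.54. The fibro-adipogenic and tenocyte list had a median log2 change of 0.26 (camera adjusted p = 5.78e-05, adjusted p = 0.487 with an estimated correlation). For collagen and matrix genes, 6 of 44 measured members were higher and 1 lower (11 and 5 adjusted over the list alone). The collagen and matrix list had a median log2 change of 0.23 (camera adjusted p = 0.0125, adjusted p = 0.696 with an estimated correlation). Its level was 0.039 and -0.095 in RP 1 and 2 and 0.26, -0.17 and -1.10 in Normal 1, 2 and 3, so the groups overlapped. It did not pass without Normal 3 or RP 1 (adjusted p = 0.572 and 0.0571, respectively). The S-adenosylmethionine decarboxylase gene Amd2, whose 3' end shares sequence with that of Amd1, had a log2 change of 2.57.

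Lower in RP were the neutrophil, erythroid, FoxO, proteasome and nerve lists, among others, while haemoglobin genes held 0.862% and 3.83% of RP counts and 11.3% ± 7.72 of those in the Normal-titled libraries. For neutrophil markers, 0 of 18 measured members were higher and 4 lower (0 and 13 adjusted over the list alone), with Chil3 at -3.73. The neutrophil list had a median log2 change of -2.32 (camera adjusted p = 1.13e-10, adjusted p = 0.432 with an estimated correlation). For erythroid markers, 0 of 17 measured members were higher and 7 lower (0 and 15 adjusted over the list alone). The erythroid list had a median log2 change of -2.30 (camera adjusted p = 3.08e-10, adjusted p = 0.432 with an estimated correlation). For FoxO target and catabolic genes, 0 of 23 measured members were higher and 4 lower (2 and 9 adjusted over the list alone). The FoxO and catabolic list had a median log2 change of -0.36 (camera adjusted p = 0.00554, adjusted p = 0.299 with an estimated correlation). For IL-6, STAT3 and acute-phase genes, 0 of 24 measured members were higher and 3 lower (0 and 12 adjusted over the list alone). The IL-6, STAT3 and acute-phase list had a median log2 change of -0.76 (camera adjusted p = 9.57e-06, adjusted p = 0.411 with an estimated correlation). For the proteasome, 0 of 41 measured members were higher and 2 lower (0 and 8 adjusted over the list alone). The proteasome list had a median log2 change of -0.38 (camera adjusted p = 1.18e-07, adjusted p = 0.456 with an estimated correlation). For Schwann and nerve markers, 0 of 18 measured members were higher and 3 lower (0 and 7 adjusted over the list alone). The Schwann and nerve list had a median log2 change of -0.72 (camera adjusted p = 9.57e-06, adjusted p = 0.432 with an estimated correlation). For the integrated stress response, 1 of 20 measured members was higher and 2 lower (2 and 5 adjusted over the list alone). The integrated stress response list had a median log2 change of -0.24 (camera adjusted p = 0.0103, adjusted p = 0.273 with an estimated correlation). For endothelial markers, 0 of 22 measured members were higher and 1 lower (0 and 4 adjusted over the list alone). The endothelial list had a median log2 change of -0.31 (camera adjusted p = 0.00608, adjusted p = 0.456 with an estimated correlation). For ribosomal proteins, 0 of 76 measured members were higher and 1 lower (0 and 0 adjusted over the list alone). The ribosomal protein list had a median log2 change of -0.28 (camera adjusted p = 6.03e-07, adjusted p = 0.638 with an estimated correlation). Its level was -0.19 and 0.038 in RP 1 and 2 and -0.13, 0.28 and 0.41 in Normal 1, 2 and 3, so the groups overlapped.

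The glucocorticoid response list had a median log2 change of -0.44 (camera adjusted p = 0.0281, adjusted p = 0.456 with an estimated correlation), with 0 of 21 members higher and 1 lower (1 and 7 adjusted over the list alone). The glucocorticoid response list did not pass without Normal 1, Normal 3 or RP 2 (adjusted p = 0.0878, 0.0693 and 0.0725, respectively). The immediate-early list had a median log2 change of -0.17 (camera adjusted p = 0.0421, adjusted p = 0.638 with an estimated correlation), with 0 of 26 members higher and 1 lower (0 and 1 adjusted over the list alone). The immediate-early list did not pass without Normal 1, Normal 2, Normal 3, Control 2 or RP 1 (adjusted p = 0.147, 0.0784, 0.0520, 0.0542 and 0.559, respectively). The adipocyte list had a median log2 change of -0.45 (camera adjusted p = 0.0429, adjusted p = 0.638 with an estimated correlation), with 0 of 23 members higher and 1 lower (1 and 1 adjusted over the list alone). The adipocyte list did not pass without Normal 1, Normal 2 or RP 2 (adjusted p = 0.439, 0.0784 and 0.204, respectively). Levels overlapped between groups for the immediate-early list (-0.39 and 0.32 in RP 1 and 2 and 0.43, 0.28 and 0.17 in Normal 1, 2 and 3) and the adipocyte list (-0.30 and -0.34 in RP 1 and 2 and 0.27, -0.055 and -0.40 in Normal 1, 2 and 3).

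The remaining lists did not pass between RP and the Normal-titled libraries. The autophagy and lysosome list had a median log2 change of -0.13 (camera adjusted p = 0.195, adjusted p = 0.456 with an estimated correlation), with 1 of 30 members higher and 2 lower (1 and 5 adjusted over the list alone). The fatty acid oxidation list had a median log2 change of -0.18 (camera adjusted p = 0.157, adjusted p = 0.696 with an estimated correlation), with 0 of 35 members higher and 1 lower (1 and 5 adjusted over the list alone). The slow-fibre list had a median log2 change of -0.25 (camera adjusted p = 0.225, adjusted p = 0.638 with an estimated correlation), with 0 of 16 members higher and 2 lower (1 and 2 adjusted over the list alone). The satellite cell list had a median log2 change of -0.32 (camera adjusted p = 0.0859, adjusted p = 0.432 with an estimated correlation), with 1 of 23 members higher and 1 lower (1 and 3 adjusted over the list alone). The denervation-responsive list had a median log2 change of -0.34 (camera adjusted p = 0.408, adjusted p = 0.638 with an estimated correlation), with 1 of 20 members higher and 1 lower (2 and 5 adjusted over the list alone). The growth signalling list had a median log2 change of -0.077 (camera adjusted p = 0.403, adjusted p = 0.638 with an estimated correlation), with 2 of 33 members higher and 2 lower (2 and 2 adjusted over the list alone). The macrophage and monocyte list had a median log2 change of -0.21 (camera adjusted p = 0.647, adjusted p = 0.918 with an estimated correlation), with 0 of 25 members higher and 0 lower (0 and 0 adjusted over the list alone). The epithelial list had a median log2 change of -0.18 (camera adjusted p = 0.732, adjusted p = 0.858 with an estimated correlation), with 0 of 6 members higher and 0 lower (0 and 0 adjusted over the list alone). The cell cycle list had a median log2 change of -0.27 (camera adjusted p = 0.445, adjusted p = 0.655 with an estimated correlation), with 1 of 32 members higher and 0 lower (1 and 1 adjusted over the list alone). The autophagy regulator Trp53inp2 was higher (1.19), as was the denervation-responsive gene Ky (1.37). Medians and means differed in sign in the next lists. The interferon response list had a median log2 change of 0.079, mean -0.027 (camera adjusted p = 0.403, adjusted p = 0.858 with an estimated correlation), with 0 of 42 members higher and 2 lower (0 and 2 adjusted over the list alone). The lymphocyte list had a median log2 change of 0.26, mean -0.0012 (camera adjusted p = 0.689, adjusted p = 0.907 with an estimated correlation), with 0 of 7 members higher and 0 lower (0 and 0 adjusted over the list alone). The clock list had a median log2 change of -0.029, mean 2.9e-04 (camera adjusted p = 0.923, adjusted p = 0.925 with an estimated correlation), with 1 of 18 members higher and 1 lower (3 and 4 adjusted over the list alone). The fatty acid oxidation list passed without Normal 3 (adjusted p = 0.00733), the slow-fibre list without Normal 1 (adjusted p = 0.0428), the satellite cell list without RP 1 (adjusted p = 0.0445) and the macrophage list without Normal 3 or RP 2 (adjusted p = 0.00506 and 0.0459, respectively).

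The position of RP between the other groups was measured next. Over the 1376 genes that differed between the Normal-titled and Control-titled libraries, with the Normal-titled mean at 0 and the Control-titled mean at 100%, the median gene stood at 72.9% in RP library 1 and 65.0% in RP library 2. These ends are extreme by the choice of genes, so, after the data were seen, each Normal-titled or Control-titled library was held out of the choice and the means in turn. Held-out libraries stood at 9.15 to 34.5% (Normal-titled) and 86.9 to 101% (Control-titled), and the RP libraries at 60.0 to 77.1% on the same scales. Of the 23 genes that differed between RP and the Control-titled libraries, 21 had also differed between the Control-titled and Normal-titled libraries, all 21 in the opposite direction, among them Trim63, Nr4a3, Ppargc1a, Hk2, Mt1, Mt2 and S100a8. Independent lists of these sizes would share 1.24 genes in opposite directions. The log2 changes correlated across genes with r of -0.58, against a mean of -0.43 over 50 simulations of groups without any effect that share the Control-titled libraries, and their covariance was -0.211 against -0.0565, a difference of -0.154; genes are not independent replicates. A pair that shares the Normal-titled libraries was added after the data were seen. Of the 330 genes that differed between RP and the Normal-titled libraries, 286 also differed between the Control-titled and Normal-titled libraries. All 286 went in the same direction from the Normal-titled libraries in both, against 17.0 for independent lists. Taken as Normal minus Control and RP minus Normal, the covariance was -0.289 against -0.0567 in the simulations, a difference of -0.232. The simulations gave each gene 1 spread for all 8 libraries, while r was 0.956 to 0.972 within the Normal-titled and 0.979 to 0.981 within the Control-titled group. The simulated covariance may therefore be too small in size for the shared Normal-titled libraries, and the difference of -0.232 too large. The groups of 3 were too small to split, so the share of the excess that comes from the shared libraries was not measured on split groups. The count of 21 was 47, 11 and 55 without Normal 1, 2 and 3, and 10, 8 and 9 without Control 1, 2 and 3. The count of 286 was 566, 131 and 455 without Normal 1, 2 and 3, 168, 187 and 164 without Control 1, 2 and 3, and 54 and 183 without RP 1 and 2.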

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

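The removal of haemoglobin genes and Rn45s, the Hba-a1 covariate and the count that shares the Normal-titled libraries were tests chosen after the results were seen. Of 1376 genes between Control-titled and Normal-titled libraries, the covariate gave 382, a threshold of 0.1 gave 2201, and leaving out 1 library gave 608 to 1858 (805 without Normal 2, 609, 846 and 608 without Control 1, 2 and 3). Of 23 genes between RP and Control-titled libraries, no filter gave 204, a mean CPM of at least 5 gave 11, DESeq2 112, limma-voom 10, only the groups compared 121, a threshold of 0.1 gave 51, and leaving out 1 library 8 to 72 (56, 12 and 72 without Normal 1, 2 and 3, and 15, 8 and 9 without Control 1, 2 and 3). Of 330 genes between RP and Normal-titled libraries, no filter gave 718, DESeq2 676, only the groups compared 100, the covariate 104, a threshold of 0.1 gave 710, and leaving out 1 library 57 to 670 (670, 137 and 580 without Normal 1, 2 and 3, 204 and 197 without Control 1 and 3, and 57 without RP 1). The 21 opposite genes that share the Control-titled libraries became 145 without a filter, 11 at a mean CPM of at least 5, 82 with DESeq2, 10 with limma-voom, 43 at a threshold of 0.1, and 8 to 55 without 1 library (47, 11 and 55 without Normal 1, 2 and 3, and 10, 8 and 9 without Control 1, 2 and 3). The 286 that share the Normal-titled libraries became 567 without a filter, 505 with DESeq2, 84 with the covariate, 569 at a threshold of 0.1, and 54 to 566 without 1 library (566, 131 and 455 without Normal 1, 2 and 3, 168, 187 and 164 without Control 1, 2 and 3, and 54 and 183 without RP 1 and 2). The 286 genes are those changed in the same direction from the Normal-titled libraries in both the Control-titled and the RP libraries. A threshold of 0.1 admits more genes by construction, and the cause of the other changes was not tested. With a replicate block the 3 counts were 1218, 17 and 262, and the 21 and 286 genes became 16 and 234. Residual correlations of libraries with the same number ran from -0.068 to 0.080, so the numbers do not pair the libraries. In camera with the block, the proteasome call of RP against Control-titled ended (adjusted p = 0.0531), while the fast-fibre, ribosomal and fibro-adipogenic lists passed (0.0201, 0.0117 and 0.0158). The collagen and adipocyte calls of RP against Normal-titled ended (0.114 and 0.109). With haemoglobin genes and Rn45s removed the counts were 1377, 29 and 340, and with RLE 1364, 29 and 320. With upper quartile they were 1376 (761 higher and 615 lower), 22 and 331.

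With an estimated correlation, camera passed 0, 0 and 0 of the 31 lists in the 3 comparisons, with 7, 5 and 4 at an unadjusted p under 0.05, and fry passed 13, 3 and 4. Results that reversed were the erythroid list between RP and Control-titled libraries without RP 2 (signed -log10 p of -0.418, the lowest over libraries left out, against a highest of 9.34 without RP 1), and, with the covariate between Control-titled and Normal-titled libraries, Sln (log2 change 0.29) and Chad (log2 change -0.0059), none of which passed. The cause was not tested. The simulated recovery of 1.5-fold changes (11.9, 10.4 and 7.46%) limits what absent calls can show.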

Other observations

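The polyamine and imprinted growth gene lists and the test of the ratio of neutrophil to haemoglobin transcripts were chosen after the results were seen. Some polyamine metabolism genes differed between the libraries titled Control and Normal. Of 11 measured, 4 were higher and 1 was lower in edgeR: Amd1 and Amd2 (log2 changes 2.82 and 2.76, with counts that cannot be separated), the spermine oxidase gene Smox (1.89) and Oaz2 (0.58) were higher in the Control-titled libraries, and the ornithine decarboxylase gene Odc1 (-0.65) was lower. Of 11 imprinted growth genes, 5 were higher and 0 lower: Dlk1 (1.41), Ndn (1.22), Rian (0.95), Mest (0.76) and Cdkn1c (0.76).

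The Normal and Control titles may have been exchanged, since the names and headers of all 6 files carry the other group's name. Under an exchange, Fbxo32 and Trim63, known to rise in tumour-bearing mice, would be lower in the Control-titled libraries, and so would neutrophil markers. Both predictions, written before the values were seen, were met at the preset correlation: the E3 ligase list was lower with an unadjusted camera p of 0.00222 and the neutrophil list with 2.45e-17, with unadjusted p of 0.0197 and 0.0497 at an estimated correlation, where neither passed after adjustment (adjusted p = 0.159 and 0.220). A real fall of both lists in tumour-bearing muscle is the biological alternative and stays untested. Fewer genes differed in edgeR between RP and the Control-titled libraries (23) than from the Normal-titled (330). This order depended on the libraries in the fit, since it turned with only the 2 groups compared (121 and 100). The main fit shared 1 spread over all 8 libraries. Libraries correlated with r of 0.956 to 0.972 within the Normal-titled and 0.979 to 0.981 within the Control-titled group. The RP libraries correlated with r of 0.965 to 0.973 with the Control-titled and 0.949 to 0.964 with the Normal-titled libraries, values that do not depend on the fit. RP libraries closer to the Control-titled ones could come from correct titles or from an exchange together with an effect of the extract. Neither the gene counts nor the correlations can tell these apart.

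Of the 10 splits of the 6 Normal-titled and Control-titled libraries into 3 and 3, 1 gave as many genes as the real split, which was the real split itself with 1376 genes. The highest of the others gave 0 in edgeR (794 at an unadjusted p under 0.05, against 3470), and 10 splits are too few for a share under 0.05.

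Neutrophil and haemoglobin transcripts were both higher in the Normal-titled libraries, and a larger amount of blood left in the muscle is a candidate explanation. More blood of 1 composition would keep the ratio of S100a8 plus S100a9 to Hba-a1, but its mean log2 was -4.74 ± 1.05 (SD, n = 3) in the Normal-titled and -9.07 ± 0.668 (SD, n = 3) in the Control-titled libraries, a difference of 4.33, which argues against the amount of blood alone. With log2 Hba-a1 as a covariate, the lower of the shares of the log2 change kept by Fbxo32 and Trim63 was 75.5%, which argues against the amount of blood as the whole cause of their difference. In RP 1 and 2 the log2 ratio of S100a8 plus S100a9 to Hba-a1 was -6.99 and -5.00. It ran from -9.64 to -8.34 in the Control-titled and from -5.96 to -4.09 in the Normal-titled libraries. Blood with more neutrophils would raise this ratio and stays open, with no other test made of it. Tumours can bring such blood, but by their titles the Normal libraries came from tumour-free mice. A tumour could then be its source only if the titles were exchanged.

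Schwann and nerve markers were lower in RP than in the Control-titled libraries, and the dissected muscle may have held less nerve. The 5 measured Schwann identity genes, chosen beforehand, had a median log2 change of -0.74 beside -1.32 for the 12 myelin genes, below the 50% of the myelin median that less nerve was set to predict, but none of the 5 passed (adjusted p 0.290 to 0.855). They ran from -1.04 to -0.23, and RP 1 lay above Control 1 for Sox10 and S100b, so less nerve stays open too. The list passed without each RP or Control-titled library in turn at the preset correlation, with a highest adjusted p of 1.94e-07, which argues against 1 library as the cause, but with all libraries and an estimated correlation it did not pass (adjusted p = 0.201). An effect of the extract on nerve stays open and was not tested.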
